A study of Arabidopsis thaliana with 18 samples.

How the data were processed

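The data were 18 ATH1 arrays of the Arabidopsis thaliana accession Kin-0, 3 biological replicates in each of 6 groups, SA in silwet or silwet alone at 4, 28 and 52 h. The authors deposited 1 table of linear intensity values with 1 column per array, and the submitters' processing notes name MAS5, with the version and target setting not given in the sources used here. The 2% trimmed mean was close to 100 on every array (100.009 to 100.011), so each array had been scaled to 1 level before it was deposited. MAS5 subtracts a background and sums probe pairs into a signal per probe set, which leaves dim probe sets noisy and spreads them widely on a log scale. The table holds no detection calls, and a value was therefore called dim where it lay below the 40th percentile of its own array. No 2 arrays were identical.

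From the deposited intensities, log2 values were taken without an offset and without further normalization. Probe sets above the 40th percentile of their array on at least 3 arrays were kept and the 64 control probe sets were left out, which left 15212 of 22746. Limma 3.58.1 in R 4.3.3 was fitted to all 18 arrays with 6 group means and no block (lmFit, and eBayes with an intensity trend). Adjusted p values are limma's, after Benjamini-Hochberg over the probe sets of 1 comparison, and a probe set was called at adjusted p under 0.05. The 8 comparisons were SA against silwet at each time, their mean, the SA effect at 28 h and at 52 h minus that at 4 h, and silwet at 28 h against 4 h and at 52 h against 28 h. Where a named gene was dim on every array of a group, its values were raised to the filter level of each array and the fold is given as at least that size.

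Gene names came from a platform annotation that lists 14016 of the 22810 probe sets, 13513 with 1 gene and 503 with several, which are named by none. Apart from the 64 control probe sets, the 8730 others are unnamed here. Symbols were updated through gene identifiers to the TAIR10.1 gene table, which matched 13436. No coordinates are printed because no build is named for the array. Of the probe sets tested, 8305 (54.6%) carried 1 gene. Of 429 members of 23 gene lists, 62 had a named probe set and 55 were tested. Camera with a preset correlation of 0.01 was run on the 10 lists with at least 3 tested members, with 1 probe set per gene, and again with a correlation estimated per list, and its p values were adjusted over the 10 lists of a comparison. Reference genes were described and not tested as a list.

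The comparisons, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. For each SA comparison the rule takes the 10 higher and 10 lower called probe sets with the largest log2 change, 1 gene and no overlap between arrays. For the mean over times it also asks for 1 side of 0 at every time. For the SA effect between times and the silwet comparisons it takes 5 and 5. It also allows any member of a fixed list. NDB2 and AT2G21640 were named after their values were seen. SARD4, ERDJ3B, UGT74C1 and the other list symbols are those of the fixed lists, and UGT74C1 is AT2G31790 in the annotation.

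Whether replicate numbers pair the arrays was checked by correlating, across probe sets, the deviations of same-numbered arrays from their group means. The correlation was above 0.1 for all 3 pairs in each comparison of 2 groups (from 0.18 to 0.71 at 4 h, 0.61 to 0.82 at 28 h, 0.20 to 0.36 at 52 h, and 0.16 to 0.63 for silwet between times), and for 41 of 45 pairs of arrays over all groups. The numbers come from the labels, and what replicates of 1 number shared is not stated there. The fit with the replicate number as a block was chosen in advance as a further fit. Its value is printed where it changed a count of called probe sets by more than 1.5 times, and for some of the single calls that it changed.

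The other fits chosen in advance used quantile normalization, median centring, an offset of 5.53 (the 20th percentile of the table), no filter, a filter at the 60th percentile, no intensity trend, array weights, only the arrays compared, a 2-fold requirement, and leaving out each array in turn. Added after seeing the data were fits without all replicate 1 arrays, with the block and without SA 4 h replicate 2, with the 3' over 5' control ratio as a covariate, and with that ratio and the block. The fits were tested on simulated data of 15212 genes, where 200 were changed at 4 h and 28 h. Replicate effects and spreads were estimated for each gene from the real data and were the same in every group. At 4 h 77 calls were made without the block, none of them an unchanged gene, and 141 with it, of which 7 were unchanged. Camera called the 1 changed set and 0 of 20 unchanged ones. The residual noise was drawn independently for each gene. This does not test camera's preset correlation where the genes of a list vary together, as some of the real lists do. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.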

Results

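Gene expression was measured on 18 ATH1 GeneChip arrays of Arabidopsis thaliana, all from the natural accession Kin-0. Plants had received 0.30 mM salicylic acid (SA), a hormone of plant defence, in 0.02% silwet, a surfactant that helps a solution spread over plant surfaces, or 0.02% silwet alone. Samples were taken 4, 28 and 52 h after treatment, which gave 6 groups of 3 biological replicates. The labels name no tissue, and untreated plants were not analysed here, so silwet alone is the background for every SA value. The series belongs to a project on differences in expression level between accessions, and its own arrays address how Kin-0 responds to SA over time. The deposited values were linear MAS5 signals for 22810 probe sets, and 15212 of them passed the filter on dim signals. The median signal of an array lay between 26.7 and 35.6, and the number of arrays, 3 per group, limits the precision of every value below.

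At 4 h the largest increases among named genes after SA were in AT3G28510, which encodes an AAA-type ATPase, in UGT76B1, a glycosyltransferase that acts on SA and related defence compounds, and in AT5G03350, which encodes a legume lectin family protein. UGT76B1 had a mean signal of 2030.4 ± 397 (SD, n = 3) after SA against 206 ± 115 after silwet, a log2 fold change of 3.46 (SE 0.76). AT5G03350 had 2525 ± 504 against 299 ± 87.3, 8.60-fold higher (SE 0.42 on the log2 scale). AT3G13610, the F6'H1 oxygenase of scopoletin synthesis, rose by 2.68 on the log2 scale (SE 0.47). Among the decreases, AT5G62360, a member of the invertase and pectin methylesterase inhibitor family, had 202 ± 75.9 against 909 ± 300.1, a log2 fold change of -2.19 (SE 0.31). All of these passed limma's test, with adjusted p between 0.00367 and 0.0461.

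In all, 121 of 15212 probe sets passed the test at 4 h, 72 higher and 49 lower after SA, and 105 of them changed at least 2-fold. In each of the 121 the 3 SA arrays lay outside the range of the 3 silwet arrays, which nearly follows from passing the test. Chance gives that separation to 10% of probe sets if arrays are independent, and it was seen for 18.0% of all those tested. The share was 2.26% at 28 h and 6.33% at 52 h, so 10% is not the level of comparisons without calls here. Besides those above, the named genes that rose were AT5G44570 (log2 fold change 2.42), AT4G32870 (2.26), AT3G62780 (1.99), AT1G15790 (4.60-fold), AT3G29240 (4.30-fold) and AT5G65530, a receptor-like cytosolic kinase. The last was below the filter level on all 3 silwet arrays and was at least 1.70-fold higher after SA. AT3G28510 (log2 fold change 3.55, SE 0.72) was below that level on 2 of the 3 silwet arrays. The named genes that fell included AT1G60590, a pectin lyase-like protein (-2.01), AT2G31790, the glucosyltransferase UGT74C1 (-1.90), AT3G55760 (-1.77), AT1G74940 (-1.71), AT1G68600, of the malate transporter family (-1.66), and AT3G19000, an oxygenase (-1.47). AT1G22550 (-1.55) and AT1G22570 (-1.45), both of the nitrate and peptide transporter family, also fell. AT3G13672 passed the test (adjusted p = 0.00447), but its signal was below the filter level on all 6 arrays and no fold is given. Among the probe sets that carry no gene name here, 249890_at (3.93) and 245035_at (3.86) rose and 254163_s_at (-2.42) fell. The unnamed 247600_at also passed (adjusted p = 0.0247), but it was below the filter level on all 3 SA arrays and 2 of the 3 silwet arrays, and at least 1.29-fold lower is all that can be said.

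Of the SA synthesis, perception and turnover list, 4 members could be tested at 4 h. UGT76B1 and SARD4, an enzyme of pipecolic acid synthesis (log2 fold change 1.52, SE 0.28), rose, while SAG101 (0.15) and BSMT1 (-1.86, SE 1.07) did not pass the test. The list as a set was higher (camera adjusted p = 0.0187), but not with an estimated correlation (adjusted p = 0.211). Of 3 genes of endoplasmic reticulum protein folding, ERDJ3B, a co-chaperone, rose (1564 ± 199.9, SD, n = 3, against 678 ± 72.6 after silwet, adjusted p = 0.00799), and CRT1B (log2 fold change 0.50) and BZIP60 (0.30) did not pass. That set was also higher (camera adjusted p = 0.0187, and adjusted p = 0.0938 with an estimated correlation). Of 3 genes of aliphatic glucosinolate synthesis, UGT74C1 fell, while BCAT4 (-0.56) and UGT74B1 (-0.54) did not pass. The set was lower (camera adjusted p = 0.00852, and adjusted p = 0.0558 with an estimated correlation). Adjusted over the list alone, these 3 lists gave the same counts of 2, 1 and 1 genes as over all genes tested. The 4 genes of abscisic acid, cold and drought response had a median log2 fold change of -0.79. None passed over all genes tested, 2 were lower when adjusted over the list alone, and the set missed the threshold (camera adjusted p = 0.0629). These set calls changed in fits with 1 array left out, which also have fewer arrays in that group. Without silwet 4 h replicate 1 the SA synthesis, folding and glucosinolate sets missed the threshold (camera adjusted p = 0.0640 for each), and without SA 4 h replicate 3 the SA synthesis and folding sets did (0.0718 for both). The abscisic acid set passed without silwet 4 h replicate 2 or 3 (0.0237 and 0.0425) or SA 4 h replicate 1 (0.00697), but with adjusted p between 0.283 and 0.401 with an estimated correlation.

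The markers of SA response could hardly be followed. PR1, PR2 and PR5, chosen as the first check of the treatment, have no named probe set in the annotation used here, and neither do most members of the other lists. The 2 of 16 SA response markers with a named probe set, WRKY53 (log2 fold change 1.70, SE 0.54) and GRX480 (1.43, SE 0.39), did not pass at 4 h (adjusted p = 0.163 and 0.0997). The other markers may be among the unnamed probe sets, so nothing is known here of their response. Genes of photosynthesis (4 tested), cell cycle (3) and glutathione transferases and detoxification (6) had none past the threshold. No marker of roots, flowers and seeds, or vascular tissue was tested, and the guard cell gene FMA had a log2 fold change of -0.47 (adjusted p = 0.391). The reference genes GAPC2 (0.03), TIP41L (0.23), UBC21 (0.29) and SAND (-0.25) did not pass either.

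With the replicate number as a block, the 4 h count was 1011 (455 higher and 556 lower), the 121 among them, and WRKY53, GRX480, BCAT4, GH3.3, COR15A and COR47 then passed (adjusted p between 0.00396 and 0.0363). The abscisic acid set then passed as well (camera adjusted p = 0.0254, but adjusted p = 0.203 with an estimated correlation). Median centring of the arrays moved the median change of all tested probe sets from -0.09 to 0.06 and left 78 calls, of which 76.9% were higher against 59.5% before. Leaving out 1 array changed much of the count and many of the named calls. Such a fit also has fewer arrays in that group, and this was not separated from the influence of the array itself. UGT76B1 and AT3G62780 missed the threshold without any 1 of the 6 arrays (adjusted p between 0.0541 and 0.218, and between 0.0691 and 0.141), AT5G65530, AT1G68600 and AT1G22570 without 5 of them, and AT3G28510, AT3G13610, AT5G44570, AT3G55760, AT3G19000 and SARD4 without 4 (SARD4 with adjusted p up to 0.111). AT1G60590, AT1G74940, AT1G22550 and ERDJ3B missed it without 3 (ERDJ3B with adjusted p up to 0.0627), UGT74C1 without 2 and AT1G15790 without 1. AT5G03350, AT4G32870, AT3G29240, AT5G62360 and AT3G13672 passed whichever of the 6 was left out. The count was 15 and 17 without silwet 4 h replicate 2 and 1, 20 and 25 without SA 4 h replicate 3 and 2, and 11 when the 6 arrays compared were fitted on their own. The SA array of replicate 2 also had the highest 3' over 5' control ratio (mean log2 2.09, against 0.80 to 1.63 on the other arrays). With that array left out and the block kept, 361 were called, 116 of the 121 among them. With the ratio as a covariate and no block, 98 of the 121 were called.

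**Figure D1:**
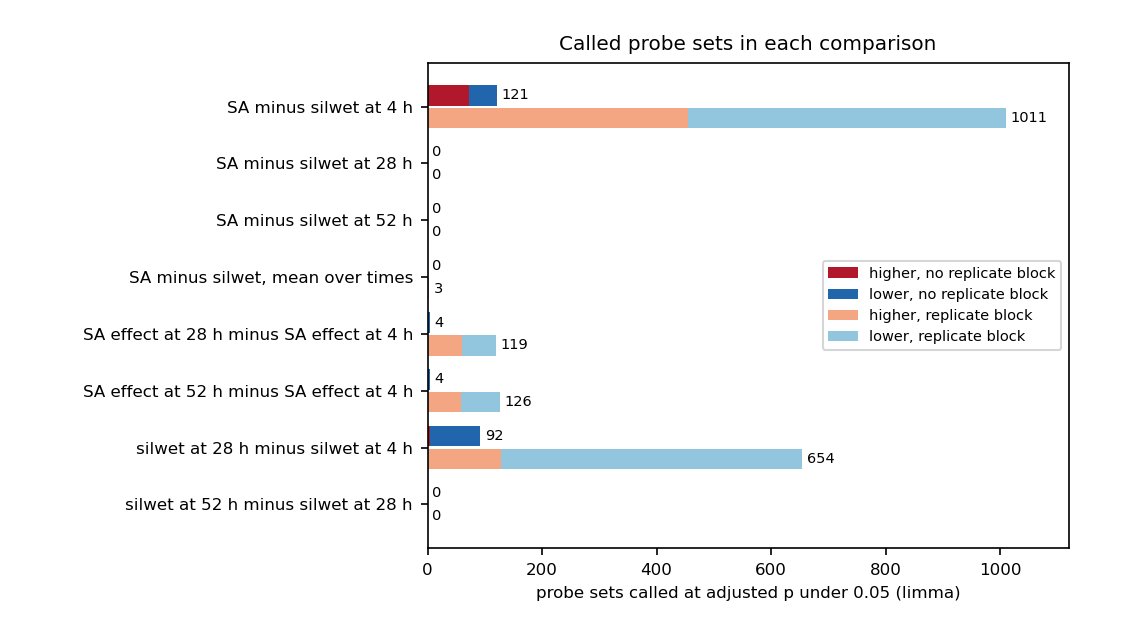
Number of probe sets called at adjusted p under 0.05 by limma in each of the 8 comparisons, as horizontal bars split into higher and lower, without and with the replicate number as a block. Calls at 4 h (121 and 1011) and between the silwet groups at 28 h and 4 h (92 and 654) stand against none at 28 h and 52 h after SA.

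At 28 h and at 52 h no gene passed the test between SA and silwet plants. UGT76B1 had 66.4 ± 18.5 (SD, n = 3) against 83.8 ± 103 at 28 h, and 13.4 ± 3.6 against 15.3 ± 12.5 at 52 h. On the log2 scale of the test the SA plants were the higher group for UGT76B1 at 28 h, where 1 silwet array lay below the filter level. At 52 h all 3 SA arrays and 2 of the 3 silwet arrays lay below it. AT5G03350 had 191 ± 115 against 224 ± 99.1 at 28 h, and 174 ± 66.2 against 161 ± 39.5 at 52 h. AT5G62360 had 1096 ± 118 against 1008 ± 144 at 28 h. The plot of the named genes at the 3 times shows the same for the others.

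Limma called 0 of 15212 probe sets at 28 h and 0 at 52 h, with or without the replicate block. At an unadjusted p under 0.05 there were 53 at 28 h and 146 at 52 h, and 141 and 642 with the block, against 761 by chance. Counts below that of chance mean that the test was conservative here, most of all at 28 h. Same-numbered arrays deviated together most strongly at that time (0.61 to 0.82). The 0 calls alone therefore do not show that SA had no effect at these times. The 121 probe sets called at 4 h had a median signed log2 change of 1.36 there, of -0.09 at 28 h and of -0.01 at 52 h. Of them 42 kept the sign of 4 h at 28 h and 59 did at 52 h, and none changed by more than 1 on the log2 scale in the direction of 4 h, against 105 at 4 h. The 121 were picked by their change on these 4 h arrays, so their size at 4 h is partly fixed by that choice. Values from arrays not used for the choice are given below. No gene list passed at 28 h or 52 h, where the lowest camera adjusted p were 0.334 and 0.227. In the simulated data every group had the same replicate effects and spreads. There 66.0% of genes changed by 2 on the log2 scale at 28 h were called without the block and 89.0% with it. For those changed by 1 the shares were 13.0% and 54.0%. In the real data the median SD within a group ran from 0.22 (silwet at 52 h) to 0.43 (silwet at 28 h). The simulated shares therefore do not give the power at 28 h.

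**Figure D2:**
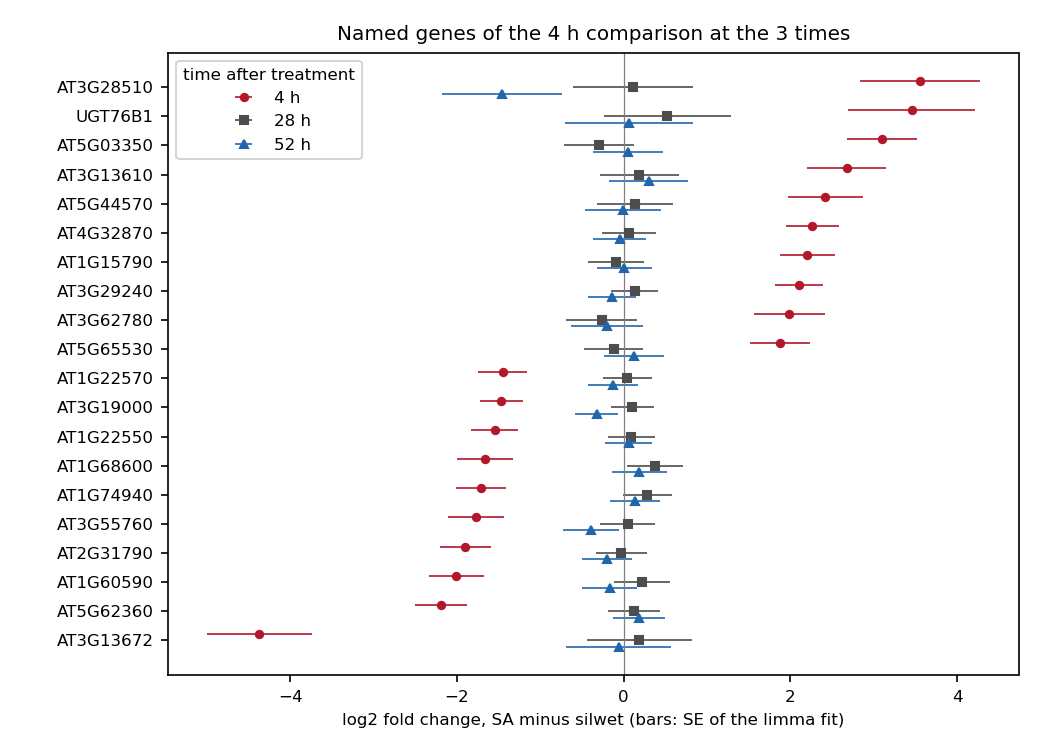
Log2 fold change of SA minus silwet (x axis) for the 20 genes named in the 4 h comparison (y axis) at 4, 28 and 52 h, with the standard error of the limma fit as bars and 3 arrays per group. The 4 h values run from -2.19 for AT5G62360 to 3.55 for AT3G28510, apart from AT3G13672, whose signal was below the filter level on all 6 arrays of 4 h, and no gene passed the test at 28 h or 52 h.

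Whether the SA effect differed between times was tested directly. AT4G02220, a zinc finger gene, had a signal of 263 ± 16.9 (SD, n = 3) after SA and 83.8 ± 8.10 after silwet at 4 h. At 28 h the values were 66.2 ± 4.74 and 74.2 ± 6.23, so the SA effect was lower by a log2 difference of -1.82 (SE 0.26, limma adjusted p = 0.0252). AT3G44190, an oxidoreductase gene, had 564 ± 59.4 and 219 ± 10.5 at 4 h against 171 ± 9.17 and 194 ± 23.7 at 28 h, a log2 difference of -1.54 (SE 0.23). At 52 h the differences from the 4 h effect were -1.65 for AT4G02220 and -1.48 for AT3G44190, with adjusted p = 0.0443 and 0.0406.

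Each of these 2 comparisons called 4 probe sets, 1 higher and 3 lower, and both use the same 6 arrays of 4 h. The other probe sets called in each were 245035_at, whose SA effect differed by -3.97 at 28 h and -3.81 at 52 h, and 254163_s_at, with 2.29 and 2.84. With the replicate block the counts were 119 and 126. With the SA and silwet labels of replicate 3 exchanged at the later time they were 346 and 403. That exchange leaves the 4 h labels, and so the 4 h effect, in place, and it cannot tell what chance gives. Leaving out single arrays gave between 0 and 5 calls for 28 h and between 0 and 11 for 52 h. AT4G02220 missed the threshold without 10 of the 12 arrays at either time, and AT3G44190 without 11 at 28 h and 10 at 52 h. The SA synthesis and folding sets had lower SA effects at 28 h than at 4 h, and the glucosinolate set higher ones (camera adjusted p = 0.0244, 0.00999 and 0.00999), with 0 members past the threshold over all genes and 2, 1 and 1 when adjusted over the list alone. With the replicate block 1 member of each set passed over all genes in the direction of its set, at 28 h and also at 52 h. The members of the SA synthesis set went apart, with UGT76B1 at -2.93, SARD4 at -1.75 and SAG101 at -0.41, but BSMT1 at 3.099 (SE 1.52). None held with an estimated correlation (adjusted p = 0.236, 0.0505 and 0.0505). At 52 h the same 3 sets passed (camera adjusted p = 0.00819 for each, and adjusted p = 0.150, 0.0631 and 0.0629 with an estimated correlation). At 28 h all 3 sets missed the threshold without silwet 4 h replicate 1 (camera adjusted p = 0.0785, 0.0531 and 0.0643) or SA 28 h replicate 1 (0.0510, 0.0503 and 0.0503). The SA synthesis set also missed it without silwet 28 h replicate 1 (0.155) or SA 4 h replicate 3 (0.0699), and at 52 h without silwet 52 h replicate 3 (0.0512). With the replicate block the abscisic acid set also passed (camera adjusted p = 0.0368 at 28 h and 0.0211 at 52 h, but adjusted p = 0.239 and 0.139 with an estimated correlation), as did the auxin set at 52 h (0.0211, and adjusted p = 0.139 with an estimated correlation). Without the block the abscisic acid set passed without silwet 4 h replicate 2, SA 4 h replicate 1, silwet 28 h replicate 1 or SA 28 h replicate 3 at 28 h (0.0166 to 0.0441). At 52 h it passed without silwet 4 h replicate 2 or 3, SA 4 h replicate 1, silwet 52 h replicate 1 or SA 52 h replicate 3 (0.0135 to 0.0496), but adjusted p was at least 0.266 with an estimated correlation in each of these fits. The auxin set passed at 52 h without silwet 4 h replicate 3 (0.0496, and adjusted p = 0.109 with an estimated correlation). For the SA effect averaged over the 3 times limma called 0 probe sets, with 633 at an unadjusted p under 0.05, and the replicate block called 3, all without a gene name here.

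Among the plants given silwet alone, expression at 4 h differed from that at 28 h mainly in genes that were higher early. AT5G51440, a small heat shock protein gene, had a signal of 313 ± 117 (SD, n = 3) at 4 h and 15.5 ± 3.85 at 28 h. MSRB9, a methionine sulfoxide reductase, had 525 ± 131 and 76.0 ± 40.4, a log2 fold change of -2.88 (SE 0.50). GSTU25, a glutathione transferase, fell by 2.32 on the log2 scale (SE 0.35). In the other direction EXPA8, an expansin that loosens the cell wall, had 88.3 ± 23.5 at 4 h and 293 ± 102 at 28 h, a log2 fold change of 1.70 (SE 0.31). The peroxidase gene AT1G71695 (0.87) and TBL36, of a family that acetylates cell wall polymers (1.34), also rose.

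Limma called 92 probe sets in this comparison, 5 higher and 87 lower at 28 h. In all 92 the 3 arrays of each group did not overlap, against 11.8% of all probe sets tested. Such separation nearly follows from passing the test and is no further support for the calls. Several of the strongest decreases ended below the filter level on all 3 arrays at 28 h, so only a lower bound holds. AT5G51440 was at least 16.1-fold lower, AT1G74870 at least 6.34-fold, CCR2, a cinnamoyl-CoA reductase of lignin synthesis, at least 2.58-fold, and the cytochrome P450 gene CYP84A4 at least 1.47-fold. The plot of every array shows the SA plants beside the silwet plants for these genes. Of 6 genes of glutathione transferases and detoxification, GSTU25 fell, DTX3 (-2.05) and UGT73B4 (-2.90) did not pass, and 4 were lower when adjusted over the list alone. The set was lower (camera adjusted p = 9.6e-05) and stayed so with an estimated correlation (adjusted p = 0.00680). Of 4 expansins and xyloglucan enzymes EXPA8 rose and 3 were higher when adjusted over the list alone. The set was higher (camera adjusted p = 6.2e-04, and adjusted p = 0.0106 with an estimated correlation). The touch and wound set (CML38 -2.50, WRKY6 -1.20, ZAT10 -1.50, none past the threshold over all genes) was lower (camera adjusted p = 0.00237). With an estimated correlation its adjusted p was 0.101. The folding set was lower too (camera adjusted p = 0.00992, and adjusted p = 0.0645 with an estimated correlation). None of its 3 members passed over all genes, and 2 were lower when adjusted over the list alone.

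With the replicate block 654 were called, 129 higher and 525 lower. Of the list members, 9 were then called lower against 1 without the block, and CML38, BZIP60, DTX3 and BIK1 (-1.62) were among those that gained a call. Under that block the expansin set missed the threshold with an estimated correlation (adjusted p = 0.0544). EXPA8 and MSRB9 missed the threshold without 3 of the 6 arrays, TBL36 and AT1G71695 without 5 and CYP84A4 without 1, and AT5G51440, AT1G74870, CCR2 and GSTU25 passed whichever was left out. Without silwet 28 h replicate 1 the SA synthesis set was lower and the cell cycle set higher (camera adjusted p = 0.00922 and 0.0343, and adjusted p = 0.102 for both with an estimated correlation). Without all arrays of replicate 1 they passed in the same directions (0.0161 and 0.0259, and adjusted p = 0.169 and 0.167 with an estimated correlation). The count was 29 without silwet 28 h replicate 2, 59 without its replicate 3, 32 and 31 without silwet 4 h replicate 2 and 3, and 4 when the 6 arrays were fitted on their own.

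**Figure D3:**
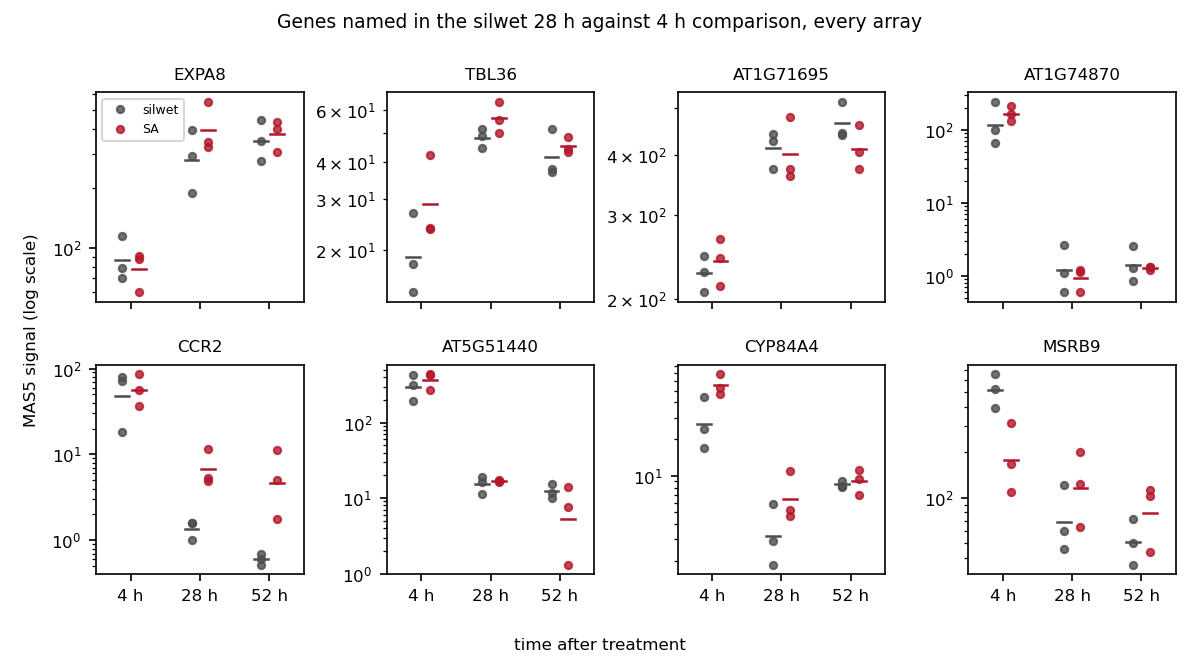
MAS5 signal on a log axis at 4, 28 and 52 h (x axis) for the 8 genes named in the comparison of silwet at 28 h with silwet at 4 h, with 1 point per array, silwet and SA plants in separate colours, and a line at the mean of the log values. EXPA8, TBL36 and AT1G71695 were higher at 28 h, and AT1G74870, CCR2, AT5G51440, CYP84A4 and MSRB9 were lower.

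From 28 h to 52 h no single gene passed in the silwet plants. UGT76B1 (log2 fold change -1.84) and the other 3 genes of its list were lower, but none passed alone. As a set they were lower (camera adjusted p = 0.00381, and adjusted p = 0.143 with an estimated correlation). The detoxification set was again lower (camera adjusted p = 0.00381, and adjusted p = 0.0359 with an estimated correlation). With the replicate block its adjusted p was 0.0195, or 0.177 with an estimated correlation. The 4 photosynthesis genes were higher as a set (camera adjusted p = 0.0217, and adjusted p = 0.233 with an estimated correlation), with 0 past the threshold alone. Limma called 0 probe sets with or without the block, with 238 and 1048 at an unadjusted p under 0.05. All 3 sets missed the threshold without silwet 28 h replicate 3 (camera adjusted p = 0.0797 for SA synthesis, 0.0850 for detoxification and 0.105 for photosynthesis). The SA synthesis and photosynthesis sets also missed it without silwet 28 h replicate 1 (0.169 for both), without silwet 52 h replicate 1 (0.0750 and 0.286) and without all arrays of replicate 1 (0.795 for both).

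**Figure D4:**
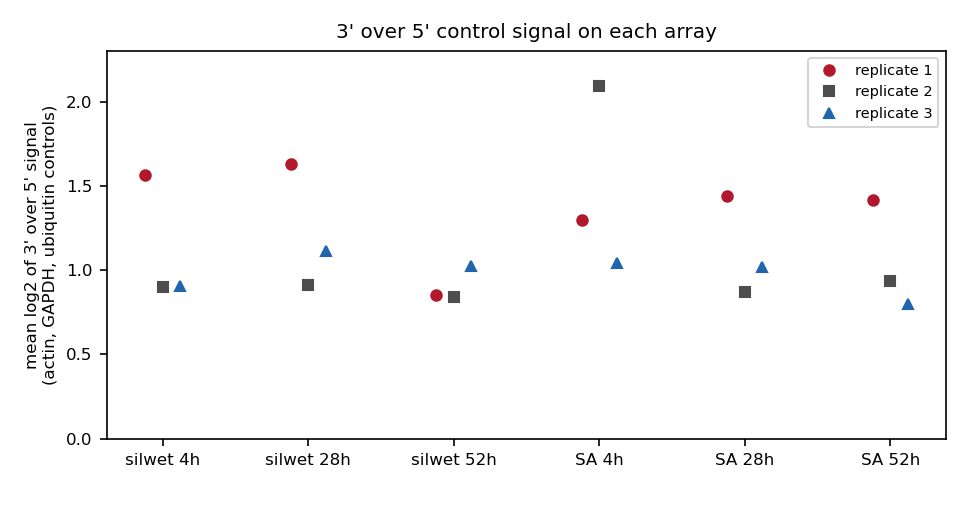
Mean log2 ratio of the 3' over the 5' signal of the actin, GAPDH and ubiquitin control probe sets (y axis) on each of the 18 arrays, by group (x axis) and replicate number. SA 4 h replicate 2 had the highest value, 2.09, and replicate 1 had the highest in 4 of the 6 groups.

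RNA quality controls varied between arrays of one group. The group means of the 3' over 5' log2 ratio ran from 0.91 ± 0.10 (SD, n = 3) for silwet at 52 h to 1.48 ± 0.55 for SA at 4 h. For silwet at 4 h and 28 h they were 1.12 ± 0.38 and 1.22 ± 0.37.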

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

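The tests that set probe sets picked at 4 h against other arrays at 28 h and 52 h, and the comparison of 3' over 5' ratios between replicate numbers and between times, were chosen after the results were seen.

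The SA effect differed between times by a test of the difference itself. For 28 h against 4 h this held for 4 probe sets: 245035_at (-3.97), 254163_s_at (2.29), AT4G02220 (-1.82) and AT3G44190 (-1.54). For 52 h against 4 h it held for 4: 245035_at (-3.81), 254163_s_at (2.84), AT4G02220 (-1.65) and AT3G44190 (-1.48). When SA and silwet labels were exchanged within times, 11 of 100 drawn splits, the real one included, gave as many calls for 28 h and 6 of 100 for 52 h. These shares do not exclude chance, but they do not measure it well either. In 8 of the 11 and all of the 6 the 4 h labels were intact, and such splits keep the 4 h effect. Of the 88 draws that changed the 4 h labels, 3 gave as many calls for 28 h and 0 for 52 h. The highest counts among those 88 were 3656 and 1. Over all drawn splits but the real one, the highest were 3656 and 33 calls. For 28 h that is far above the real count of 4. The split with 3656 calls put both replicate 1 arrays of 28 h on 1 side and both of 4 h on the other, so it follows the replicate number. Among other drawn splits that part as many pairs as the real one, the highest were 38 and 33, or 346 and 403 with the block against 119 and 126 for the real split. Those splits kept the 4 h labels and exchanged the labels of replicate 3 at the later time.

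The first pattern is 121 calls at 4 h and 0 at 28 h and 52 h. An effect of the same size hidden by a wider spread is argued against by 100 probe sets picked at 4 h without 1 pair of arrays. Their mean signed log2 difference in the held-out pair was 1.25 to 1.68 at 4 h and -0.38 to 0.23 at 28 h or 52 h. The lowest were -0.38 at 28 h in pair 1, with 14 of the 100 in the direction of 4 h, and -0.31 at 52 h in pair 2, with 20. The highest was 0.23 at 52 h in pair 3, with 71. That the response may have ended by 28 h is left open as a hypothesis. A call list made by the SA 4 h array of replicate 2 is argued against too, since 100 probe sets picked in pair 1 or pair 3 had a mean signed log2 difference of 0.70 or 0.66 in the other pair at 4 h, with 72 and 66 of the 100 in the same direction. Without that array 25 were called with no block, all among the 121, and 361 with it, 116 of the 121 among them, and 98 of the 121 stayed called with the 3' over 5' ratio as a covariate, so a part of that array in the count is not excluded. For the 6 arrays of 4 h the 10 splits are too few for a share under 0.05, and the real split gave 121 calls (1 of the 10 splits gave as many) against 2 for the highest other, or 1011 against 0 with the block among splits that part all 3 pairs.

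The second pattern is that replicates 1 and 3 stood apart, replicate 1 the most. In the blocked fit 8075 of 15212 probe sets were called between replicate 1 and replicates 2 and 3, against 335 for replicate 2 and 5128 for replicate 3. The few calls for replicate 2 mean that it mostly lay between the others, so replicate 1 was not apart alone. The explanations below were tested for replicate 1 only. Noise of dim probe sets alone is argued against, since 61.5% of the 3043 brightest were called against 51.0% of the others. A trend with the 3' over 5' ratio as the whole cause is argued against as well, because 5976 stayed called with that ratio as a covariate. Lower RNA or labelling quality of replicate 1 cannot be told apart from a difference between growth or handling batches, since replicate 1 had the highest ratio in 4 of 6 groups (exact binomial p = 0.10) and the labels do not say what a number shares. No biological explanation was tested.

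The actin control probe sets, which enter no comparison, had a log2 3' over 5' ratio of 2.80 on SA 4 h replicate 2, above the 0.56 to 0.99 on the silwet arrays of 4 h.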

How the results depend on the processing

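The fits with a 3' over 5' covariate, without replicate 1 arrays and without SA 4 h replicate 2 were chosen after seeing the data. No named gene that was called changed sign under any alternative. For SA at 4 h the count of 121 became 78 with median centring, 187 with the stricter filter, 1011 with the replicate block, 3034 with array weights, 361 with the block and SA 4 h replicate 2 left out, 364 without replicate 1 arrays, 713 with the covariate and the block, and 11 with only the arrays compared. Between 15 and 142 were called with 1 array left out. Silwet at 28 h against 4 h (92) gave 654 with the replicate block, 2333 with array weights, 655 with the block and SA 4 h replicate 2 left out, 442 without replicate 1 arrays, 699 with the covariate and block, 4 with only the arrays compared, and 29 to 110 with 1 array left out. The SA effect at 28 h minus 4 h (4) gave 2 with median centring, 119 with the replicate block, 639 with array weights, 36 with the block and SA 4 h replicate 2 left out, 0 without replicate 1 arrays, 52 with the covariate and block, 1 with only the arrays compared, and 0 to 5 with 1 array left out (at most 2 without any array but SA 4 h replicates 1 and 3). That at 52 h minus 4 h (4) gave 2 with quantile normalization and with median centring, 7 with the offset, 126 with the replicate block, 493 with array weights, 32 with the block and SA 4 h replicate 2 left out, 10 with the covariate, 128 with the covariate and block, and 0 to 11 with 1 array left out (at most 2 without silwet 4 h, SA 4 h, silwet 52 h or SA 52 h replicate 1 or 2, and 11 without SA 52 h replicate 3). The mean over times (0) gave 3 with the replicate block, 35 with array weights and 0 with any 1 array left out. SA at 28 h gave 0 throughout. SA at 52 h and silwet at 52 h against 28 h gave 0 under all alternatives but the one without silwet 52 h replicate 3, which gave 1 in each (0 to 1 with 1 array left out). The weights may be unreliable, as their estimation stopped before it converged (3034 calls at 4 h). The cause of the other changes was not tested. UGT76B1 missed the threshold without the filter, without the intensity trend, without replicate 1 arrays, with the covariate and with only the arrays compared. AT3G62780 missed it with either normalization, AT1G68600 too, and AT1G74940 and TBL36 with median centring. AT4G02220 and AT3G44190 missed it at 52 h with either normalization and at both times without replicate 1 arrays. AT3G62780 and TBL36 missed it without the filter too, AT3G13672 with the offset, CCR2 with the stricter filter and AT3G44190 at 28 h with median centring. With only the arrays compared 30 called gene results missed it. The SA synthesis set missed it at 4 h in all 4 fits chosen later (camera adjusted p = 0.0644 to 0.121), at 28 h minus 4 h in those 4, with median centring and without the filter (0.0660 to 0.440), and at 52 h minus 4 h without the filter (0.0508). The abscisic acid set passed at 4 h in the same 4, with the block, with quantile normalization and without the filter (0.0147 to 0.0430), and between times with quantile normalization (0.0272 and 0.0257), with the block and in 2 and 3 of the 4, but never with an estimated correlation (adjusted p of at least 0.139). For 6 genes named at 4 h (WRKY53, GRX480, BCAT4, GH3.3, COR15A, COR47) and 8 in the silwet comparison the block brought a call, and every gene called by the rule for named genes stayed called with it. The signal over background of dim probe sets is unknown without detection calls, which limits folds against a dim group.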

Other observations

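Grouping by the letters that start a gene symbol, and by organelle genome, was chosen after the data were seen, as were the mitochondrial list and the test with a 3' over 5' covariate below. In the silwet plants the 13 BGLU genes, which encode beta-glucosidases, were lower at 28 h than at 4 h in 12 cases (median log2 fold change -0.28, camera adjusted p = 0.0223, and adjusted p = 0.397 with an estimated correlation). The 8 PUB genes, U-box ubiquitin ligases, were lower in 7 cases (median -0.42, camera adjusted p = 0.0439, and adjusted p = 0.397 with an estimated correlation). From 28 h to 52 h, 63 of 69 genes of the plastid genome were higher (median 0.33, camera adjusted p = 1.2e-04, and adjusted p = 0.516 with an estimated correlation). The 8 ATG genes of autophagy were all lower (median -0.30, camera adjusted p = 0.0405, and adjusted p = 0.516 with an estimated correlation). Of 20 such groups in each comparison, 3 more passed the same way: SCPL was higher at 28 h (camera adjusted p = 0.0439, and adjusted p = 0.458 with an estimated correlation), and IQD was higher and VPS lower at 52 h (0.0418 for both, and adjusted p = 0.516 with an estimated correlation). No single member of these groups passed the test without the block. The mean 3' over 5' log2 ratio of the silwet arrays was 1.22 at 28 h and 0.91 at 52 h. Whether that difference bears on the plastid genes was not tested.

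The third pattern is the 87 probe sets higher at 4 h than at 28 h after silwet alone. The 10 splits of the 6 silwet arrays are too few for a share under 0.05, and the real split gave 92 calls (1 of the 10 splits gave as many) against 0 for the highest other. A difference of 3' over 5' ratio between the arrays of the times is argued against, since all 92 stayed called with the ratio as a covariate, a fit in which 2422 probe sets were called for the ratio itself. Among the genes were NDB2 (-1.09), AT2G21640 (-2.87) and AT5G51440, of mitochondrial stress, which led to the hypothesis that a mitochondrial stress response may have been higher at 4 h. Of a list of 23 such genes the 4 tested members in no other list were lower in 3 cases (median -0.58, camera p = 0.0463, and p = 0.104 with an estimated correlation), so the evidence is thin, and effects of silwet and of handling were not separated by the design.

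For the remaining comparisons the splits were as follows. SA at 28 h, SA at 52 h and silwet at 52 h against 28 h gave 0 calls in the real split and at most 0 in the others. Any split has at least 0 calls, so that 10 of 10 gave as many says nothing about chance. In any case 10 splits are too few for a share under 0.05. The mean over times gave 0 calls in the real split, so the match by 100 of 100 drawn splits is empty in the same way. The highest count was 3091, in a split that put all 6 replicate 1 arrays on 1 side, so that split follows the replicate number.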
